A study of Arabidopsis thaliana with 12 samples.

How the data were processed

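The data are 12 single-colour ATH1 GeneChip arrays of total RNA, extracted with a Qiagen RNeasy plant kit per the labels, from seedlings of Col-0, Col-7, aba2 and etr1 at 12 d and of Col-0 and ein2 at 14 d. Each of the 6 groups had 2 arrays, and the design text speaks of independent sets of arrays without saying which arrays belong to which set. Per the labels and the design text, the authors made the deposited values with Affymetrix Microarray Suite 5.0, as MAS5 signal intensity. The values themselves were linear and all above 0, and each array had the same mean of about 500.044 after trimming the lowest and highest 2%, so the deposited intensities were already scaled to a common trimmed mean. No detection calls were used here. All 12 columns of values were used.

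The table holds 22810 probe sets, of which 64 are controls and 22746 were considered. Values were brought to the common trimmed mean, which changed them very little, an offset of 50 (a fixed share of that mean) was added, and log2 was taken. Probe sets whose mean signal over the 12 arrays lay under the 40th percentile (122.3) were left out, so that 13648 were tested. Probe sets were named from the platform annotation: 13513 were paired with 1 gene, 503 with several (never named here) and 8730 were unnamed here. Of the 13513, 13436 were found in the RefSeq gene table of assembly TAIR10.1, and 1580 had a symbol other than the locus code; the rest are given by locus code. ETR1, EIN2 and ABA2 are not among the paired genes, so the level of the mutated genes could not be reported.

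Group means were compared with limma 3.58.1 in R 4.3.3: 1 fit of 6 group means to all 12 arrays (6 residual degrees of freedom, 4.35 prior degrees of freedom), eBayes with trend, two-sided tests, and Benjamini-Hochberg adjustment over the 13648 probe sets of each comparison, with a threshold of 0.05. The comparisons were etr1 with Col-0 at 12 d, ein2 with Col-0 at 14 d, aba2 with Col-7 and with Col-0 at 12 d, Col-7 with Col-0, Col-0 at 14 d with 12 d, and the 3 differences between mutant effects. The labels do not say which wild type is the control of aba2. Col-7 was chosen before the data were examined, with Col-0 as the alternative. Effects were also compared by their correlation across probe sets and by shared calls, beside the number that independent lists would share and, where comparisons shared arrays, beside the value simulated for unchanged groups. That simulation took 1 spread per probe set for all 6 groups, although replicates differed unequally between the groups. A fold change on log2(signal + 50) is smaller than the ratio of signals for dim probe sets.

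Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation; fry was run beside it. Lists with at least 3 measured members were tested. Of the 20 lists fixed before the data were examined, with 335 members, only 33 members could be paired with a probe set (1 more was left out because its symbol disagreed), and 5 lists could be tested: ABA-responsive, ethylene perception and signalling, ethylene-responsive, auxin and gibberellin. Because so few members were paired, 22 families were taken from the symbols of the named genes, of which 20 could be tested. They were chosen after the naming table was read and before any fold change was computed, and the plastid- and mitochondria-encoded families after the first values had been seen.

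Genes named in the text follow a rule set before the data were examined: the 8 largest rises and 8 largest falls per main comparison among probe sets past the threshold that are paired with 1 gene and whose arrays do not overlap between the groups; the 3 smallest p-values in a direction where fewer than 3 passed; and up to 4 members per list. Genes shared between mutants, genes whose effects differed (JAL22, DFR, COR15A), and unnamed probe sets were singled out after their values were seen.

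The procedure was tested on simulated data, with 200 of 13648 probe sets changed in each of 5 runs. The simulated noise was independent between probe sets and had the same spread in every group. On the arrays the SD of the log2 difference between replicates ran from 0.227 to 0.606. The shares recovered therefore describe the procedure and cannot tell the power of 1 comparison from that of another. In etr1 57.9% of 2-fold changes and 95.8% of 4-fold changes were recovered, in ein2 58.8% and 97.3%, in aba2 55.2% and 96.7%, and with age 54.9% and 96.7%. Changes of 1.41-fold were recovered in 2.69%, 2.39%, 2.99% and 3.28% of cases, and a median of 6, 6, 10 and 7 unchanged probe sets were called. A set of 40 independent members, each shifted 1.41-fold, was found in 5 of 5 runs in each. This does not cover smaller sets or sets of correlated members.

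Alternatives fixed beforehand were offsets of 10 and 150, quantile normalization, no filter and a filter at the 60th percentile, eBayes without trend, the replicate number as a block, fits of the compared groups alone, leaving out each array, a 2-fold rule without a test, the control of aba2, and for lists an estimated correlation and fry. Array weights, other controls for etr1 and leaving out each array for gene lists were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.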

Results

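Transcript levels were measured on 12 ATH1 arrays of whole-genome probe sets, 1 array per RNA sample, from Arabidopsis thaliana seedlings grown with 1% sucrose. The arrays form 6 groups of 2. At 12 days there were 2 wild types, Col-0 and Col-7, and the mutants aba2 and etr1. At 14 days there were the wild type Col-0 and the mutant ein2. ETR1 is an ethylene receptor and EIN2 a membrane protein that carries the ethylene signal onward. ABA2 is an enzyme of abscisic acid (ABA) synthesis. The series asks how the ABA and ethylene pathways act on each other. Each mutant was therefore compared with a wild type of its age, and the effects of the mutants were compared with each other.

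Each array had the same trimmed mean signal of 500.04 to 500.05 and a median signal between 187.9 and 213.9. Replicate arrays differed unequally: the standard deviation of the log2 difference between replicates was 0.227 in Col-0 at 14 d, 0.248 in etr1, 0.259 in ein2, 0.322 in aba2, 0.469 in Col-7 and 0.606 in Col-0 at 12 d. Between the 2 Col-0 arrays at 12 d, 1176 of 13648 probe sets were more than 2-fold apart. Col-0 replicate 1 correlated more with Col-7 replicate 1 (r = 0.9735 across probe sets, which are not independent replicates) than with its own replicate (r = 0.9112). The number of arrays limits the precision. Fold changes below are on the scale of log2(signal + 50), with standard errors from 1 limma fit to all arrays, n = 2 per group, two-sided tests and Benjamini-Hochberg adjusted p-values. That fit takes 1 spread per probe set from all 6 groups. It therefore tends to overstate the spread of ein2 and of Col-0 at 14 d and to understate that of Col-0 at 12 d. Numbers of calls are for this reason not comparable between the mutants. An exact permutation test of 2 arrays against 2 could not give a p below 0.333.

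**Figure D1:**
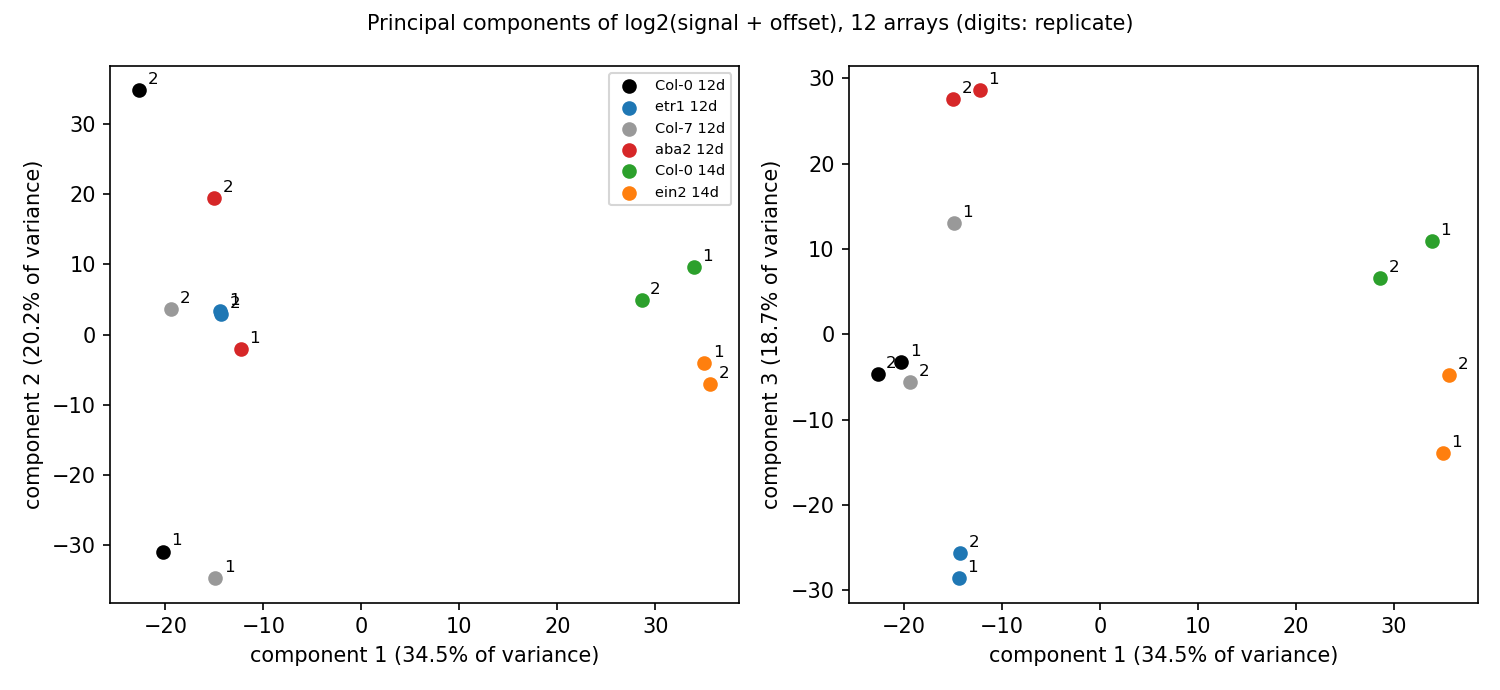
Principal components of the log2 signals of 13648 probe sets on 12 arrays, 1 point per array, coloured by group, with the replicate number beside it and component scores on the axes. Component 1 (34.5% of the variance) parted the 14 d arrays from the 12 d arrays, and on component 2 (20.2%) the 2 Col-0 arrays of 12 d lay far apart.

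The comparison of etr1 with Col-0 at 12 d asked which transcripts depend on ethylene perception. In etr1, AT3G16670 fell to a signal of 247.5 from 2096 in the wild type (log2 change -2.86 ± 0.239, adjusted p = 0.000634), a fall of 7.23-fold. AT5G50335 (-2.65 ± 0.224), AT5G57760 (-2.63 ± 0.228) and AT2G39980 (-2.53 ± 0.195) fell to signals of 20.7, 9.288 and 42.97 from 390.3, 314.6 and 487.5. These mutant signals lie below the offset of 50, which therefore largely sets the size of the change: over the alternatives it was -3.79 to -1.67, -4.15 to -1.55 and -3.23 to -1.72. A pair of genes for jacalin-related lectins, which lie close together on 1 chromosome, went opposite ways: JAL22 fell (-2.24 ± 0.187, adjusted p = 0.000634) while JAL23 rose (1.55 ± 0.191, adjusted p = 0.00853). QQS (Qua-Quine Starch, a gene that affects starch content) rose by 2.56, although its wild-type signals were spread (210.1 ± 145, SD), with 1.95 and 3.16 without Col-0 replicates 1 and 2. OPCL1, a ligase of jasmonate synthesis, rose 2.47-fold (1.3 ± 0.201, adjusted p = 0.0261). The other genes named by the fixed rule were AT1G65500 (2.50), AT2G43620 (2.27, with 2.95 and 1.58 without etr1 replicates 1 and 2), AT2G43530 (2.0), AT1G06830 (1.52) and AT2G24600 (1.33), which rose. AT1G52100 (-2.88, or -4.44 to -1.74 over the alternatives, from 385.9 to a signal of 7.595), AT4G17840 (-2.18) and AT1G62510 (-2.1) fell.

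Of the lists fixed beforehand, the ethylene-responsive genes were lower in etr1 as a set (camera adjusted p = 0.0188; adjusted p = 0.429 with an estimated correlation). Of its 3 members, 1 fell over all probe sets and 1 adjusted over the list alone. Both counts are ARL (ARGOS-like, a gene of organ size, -1.55 ± 0.197, adjusted p = 0.0103). The defensin genes PDF1.2 (-1.0) and PDF1.2b (-0.41) did not pass and hung on single arrays: without Col-0 replicates 1 and 2 they were -1.80 and -0.203, and -1.38 and 0.548. Without etr1 replicates 1 and 2 they were -0.371 and -1.63, and 0.662 and -1.49. Of the 33 ABA-responsive genes listed only 4 could be paired with a probe set, and these were also lower as a set (camera adjusted p = 0.0188, or 0.429 with an estimated correlation). None of these 4 passed over all probe sets by limma and 2 passed as lower adjusted over the list alone, COR47 (-0.88 ± 0.265) and COR15B (-0.86 ± 0.290), both cold-regulated genes. LTI30 had -0.49 and COR15A -0.31. Without Col-0 replicate 1, COR15B was -0.52, LTI30 -0.013 and COR15A 0.518, and without Col-0 replicate 2 the last 2 were -0.957 and -1.15. Ethylene perception and signalling (3 members, camera adjusted p = 0.215) had 0 over all probe sets and 1 lower adjusted over the list alone. This was RTE1 (-0.74 ± 0.169), a regulator of the receptor ETR1. The auxin list (camera adjusted p = 0.641) had 0 members over all and 1 higher adjusted over the list alone, GH3.3 (1.57 ± 0.433; 0.883 and 2.26 without Col-0 replicates 1 and 2). The gibberellin list (camera adjusted p = 0.967, median 0.03, mean -0.03) had 0 over all and 1 lower adjusted over the list alone, GID1C (-0.56 ± 0.185). Among the families added later, the plastid-encoded genes were lower as a set (median -0.29, 11 of 68 higher, camera adjusted p = 9.33e-08; adjusted p = 0.429 with an estimated correlation). The trichome birefringence-like genes were higher (median 0.17, 10 of 13 higher, camera adjusted p = 0.0489; adjusted p = 0.429 with an estimated correlation). No single member of either family passed by limma. Of these 4 sets, the plastid-encoded genes passed without each of the 4 arrays in turn (adjusted p at most 0.0476), but their median was -0.156 and -0.446 without etr1 replicates 1 and 2. The ABA-responsive set (median -0.67; -0.266 and -1.05 without Col-0 replicates 1 and 2) did not pass without Col-0 replicate 1 (0.471) or etr1 replicate 1 (0.104), nor the ethylene-responsive set without Col-0 replicate 2 (0.301) or etr1 replicate 1 (0.223). The ethylene-responsive median (-1.0) was -0.203 and -0.371 without these 2 arrays, and -1.76 without Col-0 replicate 1. Nor did the trichome birefringence-like genes pass without Col-0 replicate 1 (0.422) or etr1 replicate 1 (0.223). ARL did not pass without either etr1 array.

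In all, 63 of 13648 probe sets passed in etr1, 28 that rose and 35 that fell. At an unadjusted p under 0.05 there were 1332, where 682 would be expected with no effect. The count was 417 without Col-0 replicate 1, 104 without Col-0 replicate 2, 9 without etr1 replicate 1 and 6 without etr1 replicate 2 (62, 41, 9 and 6 of these are among the 63), and 0 in a limma fit of these 4 arrays alone. Of the 16 named genes, AT3G16670, AT5G50335, AT5G57760, AT2G39980 and JAL22 passed without each of the 4 arrays in turn.

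The comparison of ein2 with Col-0 at 14 d asked the same of a second step of the ethylene pathway. AT5G50335 fell in ein2 from a signal of 691 to 6.339 (log2 change -3.72 ± 0.224, adjusted p = 0.000114). The ein2 signals of AT5G50335 and of AT5G57760 (25.61) lie below the offset, and over the alternatives their changes were -5.50 to -2.42 and -3.7 to -1.78. AT3G16670 (-3.01 ± 0.239), AT5G57760 (-2.73 ± 0.228), AT5G62280 (-2.26 ± 0.160) and AT2G39980 (-1.88 ± 0.195) fell as well, and so did ARL (-1.99 ± 0.197, adjusted p = 0.00173), AT3G12710 (-1.64) and SIS (Salt Induced Serine rich, -1.60 ± 0.262, adjusted p = 0.0321). JAL23 rose 4.95-fold (2.31 ± 0.191, adjusted p = 0.000409), and DFR, the dihydroflavonol reductase of anthocyanin synthesis, rose 3.73-fold (1.90 ± 0.319, adjusted p = 0.0370). AT5G62130 (2.49), AT1G19960 (2.27), AT1G52000 (2.08), AT1G66100 (1.56) and AT1G54050 (1.23) rose too.

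As a set, the 3 ethylene-responsive genes were lower in ein2 (camera adjusted p = 0.00896; adjusted p = 0.25 with an estimated correlation). Here too 1 fell over all probe sets and 1 adjusted over the list alone, ARL. PDF1.2b had -0.48, which was also the median of the list, and PDF1.2 -0.15. Without Col-0 replicates 1 and 2 the list's median was -0.769 and -0.195, and without ein2 replicate 2 it was -0.264. PDF1.2 turned to 0.317 without Col-0 replicate 2 and 0.091 without ein2 replicate 2, and was -0.617 and -0.391 without the replicates 1. The xyloglucan endotransglucosylase genes, whose enzymes remodel cell walls, were lower as a family (median -0.65, 1 of 5 higher, camera adjusted p = 0.00896; adjusted p = 0.164 with an estimated correlation), with XTH18 at -1.37 ± 0.455 (-0.859 without ein2 replicate 1) and XTH16 at -1.02 ± 0.279. Beta-glucosidases (9 of 9 higher, median 0.25; BGLU28 at 1.0 ± 0.347, and 0.512 without Col-0 replicate 2) and UDP-glycosyltransferases (19 of 25 higher, median 0.15) were higher, each with a camera adjusted p = 0.00896 and an adjusted p = 0.164 with an estimated correlation. The plastid-encoded genes were higher (54 of 68 higher, median 0.24, camera adjusted p = 9.66e-08; adjusted p = 0.264 with an estimated correlation). So were the mitochondria-encoded genes (11 of 11 higher, median 0.30, camera adjusted p = 0.00896; adjusted p = 0.294 with an estimated correlation). The WRKY transcription factors were lower (1 of 6 higher, median -0.28, camera adjusted p = 0.0412; adjusted p = 0.25 with an estimated correlation). The trichome birefringence-like genes were higher (8 of 13 higher, median 0.20, camera adjusted p = 0.0412; adjusted p = 0.294 with an estimated correlation). Apart from ARL, no single member of these lists passed over all probe sets by limma. The other fixed lists did not pass as sets. The ABA-responsive list (camera adjusted p = 0.333) had 0 members over all and 1 higher adjusted over the list alone, COR15A (1.59 ± 0.461). Ethylene perception and signalling (0.0948) had 0 over all and 1 lower adjusted over the list alone, RTE1 (-0.54 ± 0.169; -0.351 without ein2 replicate 1). Auxin (0.831) and gibberellin (0.58) had 0 over all and 0 adjusted over the list alone. The plastid-encoded, mitochondria-encoded and xyloglucan endotransglucosylase sets passed without each of the 4 arrays in turn (adjusted p at most 0.0343), with a plastid-encoded median of 0.152 and 0.367 without ein2 replicates 1 and 2. Without Col-0 replicate 2 the ethylene-responsive genes, beta-glucosidases, WRKY factors and trichome birefringence-like genes did not pass (each 0.0711). The last 2 did not pass without Col-0 replicate 1 either (0.0883, with a WRKY median of -0.186, and 0.0878). The same held for the UDP-glycosyltransferases (0.0689) and WRKY factors (0.391, with a median of only -0.073) without ein2 replicate 1, and for the trichome birefringence-like genes (0.157) without ein2 replicate 2.

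Across the array, 51 probe sets passed in ein2, 14 that rose and 37 that fell. At an unadjusted p under 0.05 there were 733, against 682 expected. Because the pooled spread tends to overstate that of these 4 arrays, the 733 do not show that ein2 had little effect. The count was 15 without Col-0 replicate 1, 17 without Col-0 replicate 2, 17 without ein2 replicate 1 and 12 without ein2 replicate 2, and 368 in a fit of these 4 arrays alone. Of the 15 named genes, JAL23, AT5G50335, AT3G16670, AT5G57760, AT5G62280 and ARL passed without each of the 4 arrays in turn.

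Between etr1 and ein2, measured at different ages against separate wild-type arrays, 24 probe sets passed in the same direction and 0 in opposite directions by limma, where independent lists would share 0.124. Of these 24, 19 fell in both mutants, among them AT3G16670, AT5G50335, AT5G57760, AT2G39980, AT5G62280 (-2.09 in etr1, -2.26 in ein2) and ARL (-1.55 and -1.99). IAGLU, for an enzyme that joins glucose to the auxin indole-3-acetic acid, fell by 1.59 and 1.26 on the log2 scale. AT3G54040 (-1.10 and -1.48) and AT3G12710 (-1.10 and -1.64) fell too. The 5 that rose in both included JAL23. All 51 probe sets that passed in ein2 had the same sign in etr1, and 53 of the 63 that passed in etr1 had the same sign in ein2. Across all probe sets, which are not independent replicates, the effects correlated at r = 0.407 (Spearman's rho 0.288). JAL22 was 1 of only 2 probe sets whose effect differed between the mutants by a test of the difference. It was -2.24 in etr1 and 0.64 in ein2 (difference -2.88 ± 0.264, adjusted p = 0.00728). The other was an unnamed probe set (-0.19 in etr1, -2.24 in ein2, difference 2.05 ± 0.236, adjusted p = 0.0303). By list, the ABA-responsive genes differed (lower in etr1, camera adjusted p = 5.21e-04; adjusted p = 0.113 with an estimated correlation), as did the plastid-encoded genes (lower in etr1, camera adjusted p = 2.52e-21; adjusted p = 0.113 with an estimated correlation). The cold and dehydration genes were lower in etr1 than in ein2 (camera adjusted p = 0.0429, or 0.374 with an estimated correlation). This list of 8 shares members with the ABA-responsive list (lowest member -1.91 in both), so it is not a separate result. The xyloglucan endotransglucosylase genes were higher in etr1 (0.0429, or 0.254 with an estimated correlation).

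The number shared in the same direction was 53 without Col-0 12 d replicate 1, 6 and 5 without etr1 replicates 1 and 2, 10 and 7 without ein2 replicates 1 and 2, and 8 and 9 without Col-0 14 d replicates 1 and 2. The correlation was 0.118 without Col-0 12 d replicate 2. The count of 2 differences was 12 without that array, 3 without Col-0 12 d replicate 1, 1 without etr1 replicate 1, and 0 by limma without etr1 replicate 2, either ein2 array or either Col-0 14 d array. Of the 4 sets that differed, the plastid-encoded genes passed without each of the 8 arrays in turn. The ABA-responsive genes did not pass without Col-0 12 d replicate 1 (0.0577). The cold and dehydration genes passed only without ein2 replicate 2 or Col-0 12 d replicate 2 (otherwise up to 0.564). The xyloglucan endotransglucosylase genes passed only without Col-0 14 d replicate 2, ein2 replicate 2 or etr1 replicate 1 (otherwise up to 0.334).

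**Figure D2:**
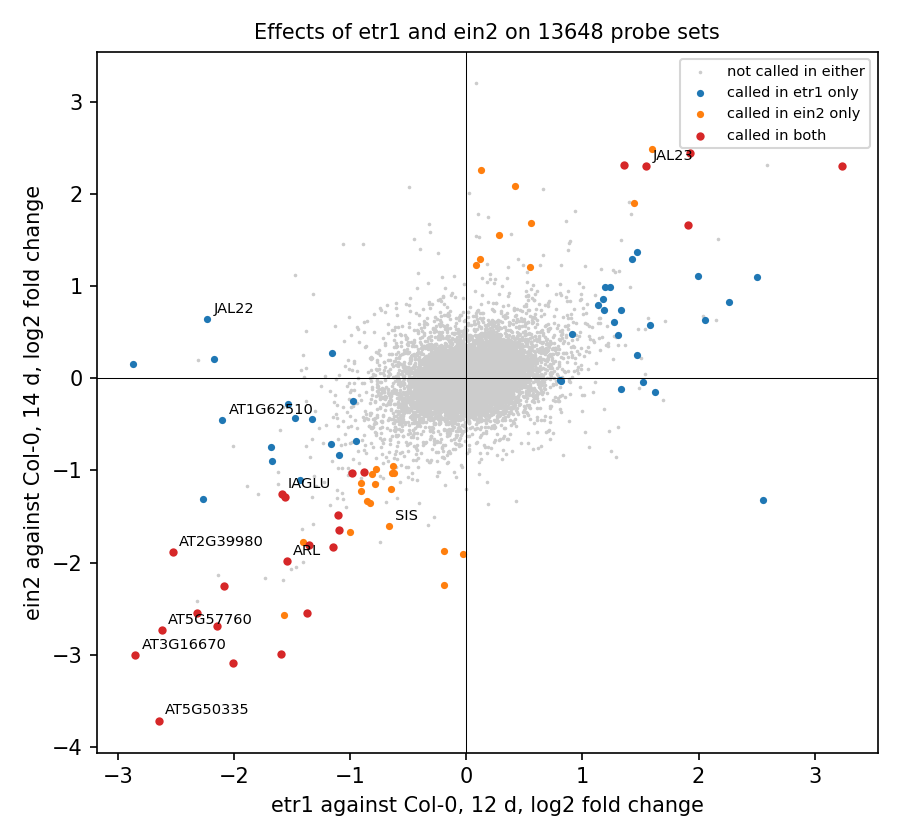
Log2 fold change in etr1 against Col-0 at 12 d (horizontal axis) and in ein2 against Col-0 at 14 d (vertical axis), 1 point per probe set, coloured by the comparison in which it passed. The 24 probe sets that passed in both lie in the quadrants of equal sign, and JAL22 lies at -2.24 in etr1 and 0.64 in ein2.

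The comparison of aba2 with Col-7 at 12 d asked which transcripts change when ABA synthesis is impaired. Among those that rose were AT5G28630 (4.36-fold, 2.12 ± 0.299, adjusted p = 0.0196), AT3G16530 (4.28-fold, 2.1 ± 0.258, adjusted p = 0.0140), CML42, a calmodulin-like calcium-binding protein (1.56 ± 0.222, adjusted p = 0.0196), and SIS (1.51 ± 0.262, adjusted p = 0.0390). AT1G80130 fell 5.17-fold (-2.37 ± 0.389, adjusted p = 0.0312), and JAL23 fell 2.78-fold, from a signal of 434.7 to 124.5 (-1.48 ± 0.191, adjusted p = 0.0172). AT1G26380 (1.86), AT1G05575 (1.81), AT2G25735 (1.69) and AT4G20830 (1.54) rose. AT3G53980 (-1.71), AT1G62510 (-1.70), AT1G73040 (-1.46) and AT1G64360 (-1.41) fell. The cold-regulated gene COR15A was 5.43-fold lower at -2.44 ± 0.461 but did not pass (adjusted p = 0.0563), nor did DFR at -1.57 ± 0.319 (adjusted p = 0.0670).

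The 4 ABA-responsive genes did not pass as a set in aba2 (camera adjusted p = 0.873, with a median of 0.10 but a test direction of down). None passed over all probe sets by limma (0 of 4). Adjusted over the list alone 1 was higher, LTI30 (0.78 ± 0.295), and 1 lower, COR15A. In the gibberellin list (camera adjusted p = 0.1) 0 passed over all and 2 were higher adjusted over the list alone. These were the gibberellin receptors GID1B (0.59 ± 0.180) and GID1A (0.54 ± 0.191), which were 0.371 and 0.355 without Col-7 replicate 1. The lists for auxin (0.685), ethylene perception and signalling (0.486) and ethylene-responsive genes (0.873) had 0 members over all and 0 adjusted over the list alone. Plastid-encoded genes were lower in aba2 as a set (5 of 68 higher, median -0.40, camera adjusted p = 4.71e-11; adjusted p = 0.404 with an estimated correlation), with rps2 at -1.10 ± 0.214. Mitochondria-encoded genes were lower too (1 of 11 higher, median -0.39, camera adjusted p = 0.0276; adjusted p = 0.587 with an estimated correlation). No member of either family passed by limma against Col-7. Fry ranked other families first, with an unadjusted p = 0.00237 for calmodulin-like genes and 0.00251 for xyloglucan endotransglucosylase genes (4 of 5 higher in each). By fry the plastid-encoded set had 0.0195 and the mitochondria-encoded set 0.0544. By camera the adjusted p was 0.1 for the calmodulin-like and 0.0969 for the xyloglucan endotransglucosylase genes. The plastid-encoded set passed without each of the 4 arrays in turn, but the mitochondria-encoded set did not without Col-7 replicate 2 (0.449, with a median of -0.202) or aba2 replicate 2 (0.124).

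In total, 62 probe sets passed in aba2 against Col-7, 34 that rose and 28 that fell. At an unadjusted p under 0.05 there were 1680, against 682 expected. Against Col-0, the other wild type of 12 d, 221 passed, 186 that rose and 35 that fell. Against both, 43 passed in the same direction, 30 higher and 13 lower, and all 62 had the same sign against Col-0. Both comparisons use the same aba2 arrays, which alone favours such agreement, and no value for unchanged groups was simulated for this pair. SIS was 3.09 ± 0.262 higher against Col-0. JAL23 did not pass against Col-0 (-0.86 ± 0.191, limma adjusted p = 0.0574). The count against Col-7 was 4 without either aba2 array and 7 in a fit of the 4 arrays alone. Without Col-7 replicate 1 it was 56 (16 that rose and 40 that fell), of which 22 are among the 62, and without Col-7 replicate 2 it was 58 (41 and 17), of which 28 are. None of the 14 named genes passed without each of the 4 arrays in turn. Against Col-0 the count was 481 and 586 without Col-0 replicates 1 and 2 (175 and 186 of them among the 221), and 54 and 68 without aba2 replicates 1 and 2, and 6 in a fit of these 4 arrays alone.

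Set against ein2, aba2 shared calls in opposite directions, while against etr1 the balance depended on the control arrays. JAL23 rose in etr1 and ein2 and fell in aba2 against Col-7. The difference was -3.78 ± 0.269 for aba2 minus ein2 (adjusted p = 0.000205) and -3.03 ± 0.269 for aba2 minus etr1 (adjusted p = 0.00147). Against Col-0 the change of JAL23 in aba2 was -0.86 and did not pass. SIS fell in ein2 and rose in aba2 (difference 3.11 ± 0.370, adjusted p = 0.00522). DFR was higher in ein2 and not called in aba2, and its effects differed by -3.47 ± 0.452 (adjusted p = 0.00742), while COR15A, called in neither, differed by -4.03 ± 0.651 (adjusted p = 0.0204). AT2G24600 rose in both aba2 (1.47) and etr1 (1.33), and AT1G62510 fell in both (-1.70 and -2.1). These were the only 2 probe sets called in the same direction in aba2 and etr1.

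Between aba2 and ein2, 0 probe sets were called by limma in the same direction (733 and 1680 had an unadjusted p under 0.05) and 5 in opposite directions, where independent lists would share 0.121. These 5 were JAL23, SIS, an unnamed probe set at -2.72 in aba2 and 2.32 in ein2, another at -3.58 and 2.44, and 1 that is paired with several genes. Of the 108 called in either, 82 had opposite signs, and the effects correlated at r = -0.355 across probe sets (Spearman's rho -0.287). Between aba2 and etr1, 2 were called in the same and 5 in opposite directions, with r = -0.0444. Against Col-0 in place of Col-7, aba2 and ein2 shared 0 calls by limma in the same and 6 in opposite directions, with r = -0.207. There aba2 and etr1 shared 6 in the same and 2 in opposite directions, and r was 0.11, where sharing the Col-0 arrays alone gave a simulated r of 0.501 (covariance 0.0143 against a simulated 0.0296). The difference between effects passed for 143 probe sets between aba2 and ein2 (77 higher in aba2, 66 lower) and for 62 between aba2 and etr1 (37 and 25). By list, aba2 differed from ein2 in plastid-encoded genes (lower in aba2, camera adjusted p = 3.54e-14; adjusted p = 0.269 with an estimated correlation). They also differed in mitochondria-encoded genes (0 of 11 higher in aba2, median difference -0.64, camera adjusted p = 0.00172; adjusted p = 0.317 with an estimated correlation) and in xyloglucan endotransglucosylase genes (higher in aba2, camera adjusted p = 0.00832; adjusted p = 0.269 with an estimated correlation). From etr1, aba2 differed in autophagy genes (8 of 10 higher in aba2, median difference 0.60) and mitochondria-encoded genes (0 of 11 higher, -0.53), each with a camera adjusted p = 0.0368 and an adjusted p = 0.508 with an estimated correlation.

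The 143 differences numbered 25 and 35 without Col-0 14 d replicates 1 and 2, 39 and 25 without ein2 replicates 1 and 2, and 33 and 38 without aba2 replicates 1 and 2. The 62 differences numbered 851 and 95 without Col-0 12 d replicates 1 and 2, 116 without Col-7 replicate 1, 15 and 16 without aba2 replicates 1 and 2, and 16 and 15 without etr1 replicates 1 and 2. Of the opposite calls of aba2 and ein2, 2 were left without Col-0 14 d replicate 1 or 2, ein2 replicate 1, or aba2 replicate 1 or 2, 1 without ein2 replicate 2, and 9 were found without Col-7 replicate 2. For aba2 and etr1, r was -0.282 without Col-0 12 d replicate 1 and 0.226 without replicate 2, -0.159 and 0.0698 without Col-7 replicates 1 and 2, -0.0121 without aba2 replicate 2. Opposite calls numbered 43 and 5 without Col-0 12 d replicates 1 and 2, 10 and 3 without Col-7 replicates 1 and 2, and 0 by limma without any 1 of the aba2 or etr1 arrays. Calls in the same direction numbered 9 and 10 without Col-0 12 d replicates 1 and 2, 2 and 3 without Col-7 replicates 1 and 2, and 0 by limma without any 1 of the aba2 or etr1 arrays. For aba2 and ein2 there was 1 such call without Col-7 replicate 1. Of the sets that differed between aba2 and ein2, the xyloglucan endotransglucosylase genes did not pass without aba2 replicate 1 (0.0685), and the other 2 passed without each of the 8 arrays in turn, the mitochondria-encoded genes with a median of -0.403 without Col-7 replicate 2. Between aba2 and etr1, the autophagy genes did not pass without Col-0 12 d replicate 2 (0.488), Col-7 replicate 1 (0.154) or aba2 replicate 2 (0.108). The mitochondria-encoded genes did not without Col-0 12 d replicate 1 (0.262, median -0.34), Col-7 replicate 2 (0.317, median -0.343), aba2 replicate 2 (0.119) or etr1 replicate 2 (0.117).

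**Figure D3:**
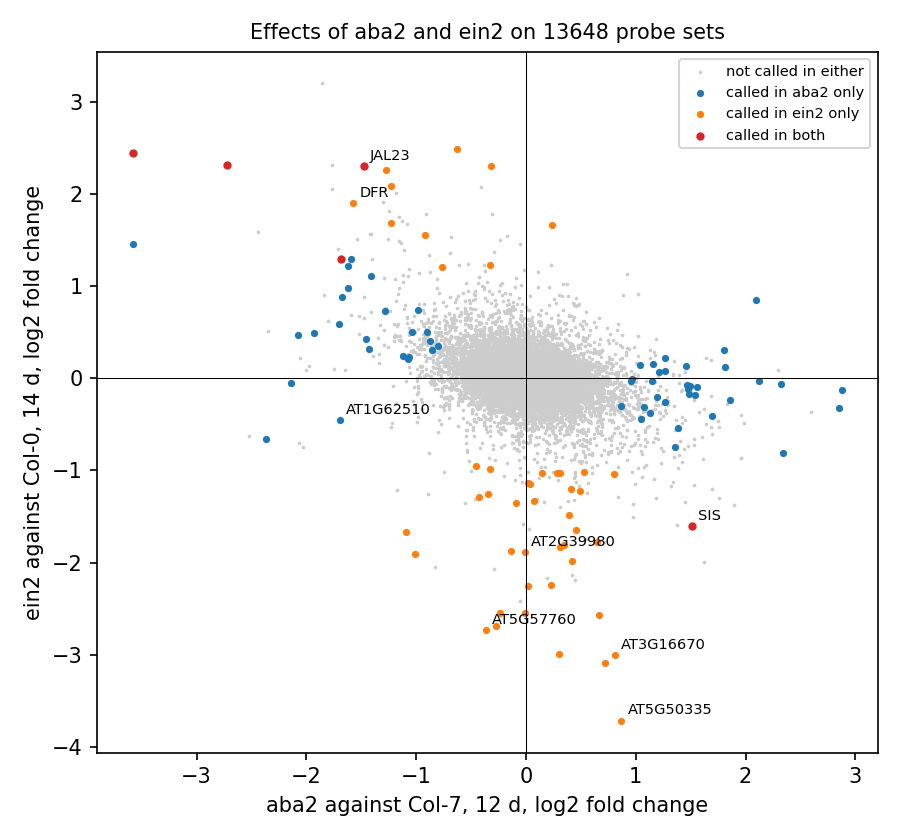
Log2 fold change in aba2 against Col-7 at 12 d (horizontal axis) and in ein2 against Col-0 at 14 d (vertical axis), 1 point per probe set, coloured by the comparison in which it passed. The 5 probe sets that passed in both lie in the quadrants of opposite sign, across an r of -0.355 for all probe sets.

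**Figure D4:**
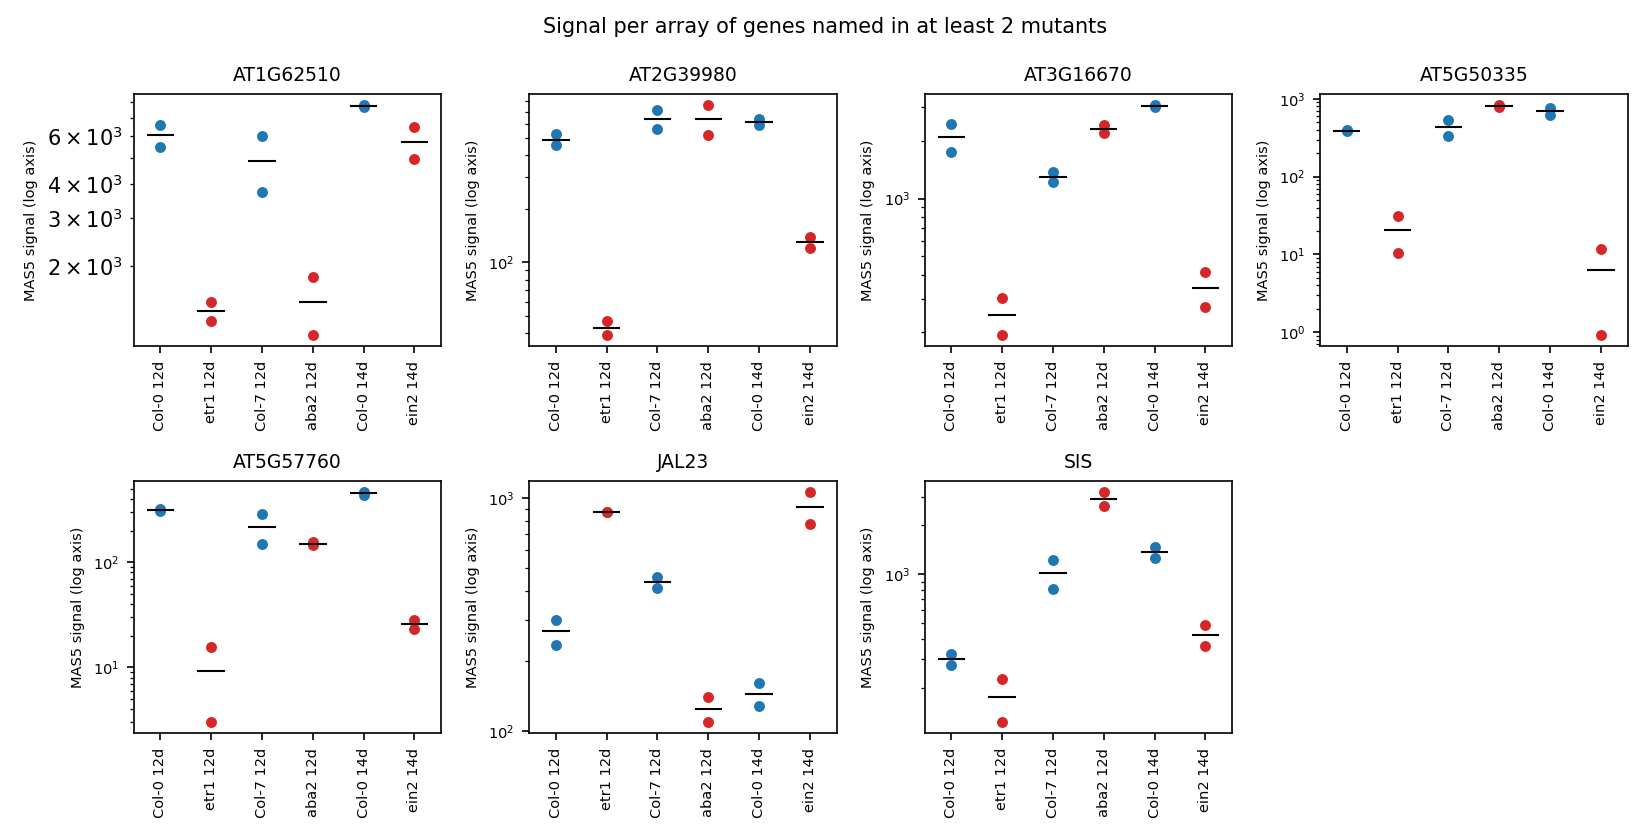
Deposited MAS5 signal per array, on a logarithmic axis, of the genes that the naming rule took in at least 2 of the 3 mutants, with wild types in blue, mutants in red and a bar at each group's mean. JAL23 averaged 875.6 in etr1 and 919.6 in ein2 but 124.5 in aba2.

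Col-7 and Col-0 at 12 d were compared as a check of the wild types against each other. WRKY53, a transcription factor linked to senescence, averaged a signal of 372.7 in Col-7 and 89.85 in Col-0 (1.59 ± 0.211, adjusted p = 0.103). The pseudogene AT1G43590 averaged 464.5 and 82.01 (1.96 ± 0.254, adjusted p = 0.103). Neither passed, and nor did SRC2 (1.07), AT3G49960 (-1.15), AT1G04945 (-0.82) or AT2G43770 (-0.62). Across all 13648 probe sets limma called 0, with 654 at an unadjusted p under 0.05 where 682 would be expected. Without Col-0 replicate 1 it called 465, and without Col-7 replicate 1 it called 1. The 6 WRKY factors were all higher in Col-7 (median 0.28, camera adjusted p = 0.00538; adjusted p = 0.267 with an estimated correlation). The median was 0.503 and 0.14 without Col-7 replicates 1 and 2, and the set did not pass without Col-7 replicate 2 (0.235) or Col-0 replicate 1 (0.262). The autophagy genes were lower (1 of 10 higher, median -0.31, camera adjusted p = 0.0120; adjusted p = 0.843 with an estimated correlation). This rested on Col-0 replicate 2, without which the median was -0.047 and the test direction turned to up (adjusted p = 0.886), against -0.498 without Col-0 replicate 1. Nor did it pass without Col-7 replicate 1 (0.292) or 2 (0.105). None of the 5 fixed lists passed as a set (camera adjusted p from 0.518 for ethylene perception and signalling to 0.759 for auxin), with 0 members over all probe sets and 0 adjusted over the list alone.

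Col-0 at 14 d was compared with Col-0 at 12 d, which describes how the 2 wild-type controls of the ethylene mutants differed. AT4G29780 rose 13.3-fold (3.73 ± 0.629, adjusted p = 0.00732), and STZ, a zinc finger gene of stress responses also called ZAT10, rose by 2.99 ± 0.754 (adjusted p = 0.0430). WRKY53 rose 5.26-fold (2.40 ± 0.211, adjusted p = 0.000562) and the wall-remodelling genes XTH18 and XTH19 rose by 2.96 ± 0.455 and 2.02 ± 0.306 on the log2 scale. The defensin gene PDF1.2 fell to a signal of 44.91 from 954.6 (-3.27 ± 0.713, adjusted p = 0.0242). COR15A fell (-2.50 ± 0.461, adjusted p = 0.0108), by -1.67 and -3.33 without Col-0 12 d replicates 1 and 2, and did not pass without either 14 d array. The gene rpl16, for a plastid ribosomal protein, fell 4.59-fold (-2.20 ± 0.275, adjusted p = 0.00186). AT2G22880 (3.46), the carnitine transporter gene OCT1 (3.35), AT2G24600 (3.07), AT3G02840 (3.02), AT5G17350 (3.01) and AT3G10930 (3.01) rose. AT4G12490 (-3.13), AT1G76960 (-2.01), AT1G26250 (-1.96), AT1G19960 (-1.77) and AT1G56300 (-1.72) fell. Where 1 age had a signal below the offset, the change over the alternatives was -4.15 to -2.35 for PDF1.2, -3.19 to -1.16 for AT1G76960, 2.35 to 4.65 for AT2G22880 and 2.03 to 3.99 for AT3G02840. The 2 Col-0 arrays of 12 d also moved OCT1 (2.34 and 4.35 without replicates 1 and 2) and PDF1.2 (-4.07 and -2.47), and those of 14 d moved AT1G26250 (-1.28 and -2.63). Neither STZ nor PDF1.2 passed without either 14 d array or without Col-0 12 d replicate 2.

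Plastid-encoded genes were lower at 14 d as a set (15 fell and 2 rose of 68, camera adjusted p = 6.65e-09; adjusted p = 0.315 with an estimated correlation), among them atpB (-0.87 ± 0.129) and rps2 (-1.29 ± 0.214). Mitochondria-encoded genes were higher (3 of 11 rose, nad1, ccb452 and nad4L, camera adjusted p = 0.0257, or 0.361 with an estimated correlation). Adjusted over the list alone 4 were higher and 1 lower, and the lowest member was at -1.205. Their median of 0.391 was 0.203 and 0.688 without Col-0 12 d replicates 1 and 2. The calmodulin-like genes (3 of 5 rose: CML38 at 2.70, CML23 at 1.26 and CML42 at 0.85) and the WRKY factors (2 of 6 rose: WRKY53 and WRKY22 at 1.92) were higher, each with a camera adjusted p = 0.0257 and an adjusted p = 0.315 with an estimated correlation. Of the fixed lists none passed as a set. The ABA-responsive list (0.233) had 2 members that fell over all and 2 adjusted over the list alone, COR15A and COR15B (-1.19). The ethylene-responsive list (0.376) had 1 that fell over all, PDF1.2. Adjusted over the list alone it had 1 higher, ARL (0.69), and 2 lower, PDF1.2 and PDF1.2b (-2.75; -3.71 and -1.78 without Col-0 12 d replicates 1 and 2). In the auxin list (0.504) 1 rose, WES1 (1.0, and 0.616 without Col-0 12 d replicate 1), and in the gibberellin list (0.7) 1 rose, GID1B (0.79), with 1 in each adjusted over the list alone. Ethylene perception and signalling (0.817) had 0 over all and 0 adjusted over the list alone. Fixed lists with too few measured members for a set test had single genes that passed. The clock gene GI (GIGANTEA) fell (-0.95 ± 0.160, adjusted p = 0.00727) and the light-harvesting gene LHCB4.1 fell (-0.51 ± 0.120, adjusted p = 0.0330). DFR fell (-1.51 ± 0.319, adjusted p = 0.0212) and the glutaredoxin gene GRX480 rose (1.06 ± 0.180, adjusted p = 0.00792). The plastid-encoded set passed without each of the 4 arrays in turn. The other 3 did not pass without Col-0 14 d replicate 2 (0.0546 to 0.0694) or 12 d replicate 1 (0.0843 to 0.182), nor the calmodulin-like genes (0.107) and WRKY factors (0.0639) without 12 d replicate 2. Of the members named in this paragraph that were called over all probe sets, atpB, CML38 and WRKY53 passed without each array in turn, as did rpl16 named above. The other called members named in this paragraph did not pass without Col-0 14 d replicate 1. WRKY22 was 1.22 and 2.62 without Col-0 12 d replicates 1 and 2.

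With age, 885 probe sets passed, 629 that rose and 256 that fell. At an unadjusted p under 0.05 there were 2783, against 682 expected. The count was 143 and 319 without Col-0 14 d replicates 1 and 2, 1217 and 1462 without Col-0 12 d replicates 1 and 2 (631 and 680 of them among the 885) and 121 in a fit of these 4 arrays alone. AT2G22880, AT2G24600, AT3G02840 and rpl16 passed without each of the 4 arrays in turn. All 14 d arrays also differed from all 12 d arrays in the signal of bioC, a bacterial control transcript added before hybridization (1004 to 1145 against 351.5 to 552). It was the only 1 of 4 spiked transcripts compared that did so. Age therefore cannot be told apart from a possible difference in processing.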

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

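All tests of explanations in this part, and the 11 control probe sets looked at among the 64, were chosen after the results had been seen; the tests of differences between mutant effects were fixed before the data were examined.

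The effects of aba2 and ein2 differed by a direct test for 143 probe sets, those of aba2 and etr1 for 62, and those of etr1 and ein2 for 2. JAL23, SIS and DFR are among the first group, and JAL22 is 1 of the last 2.

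For the opposite effects of aba2 and ein2 (r = -0.355), which share no arrays, removing from both the difference between the 2 Col-0 12 d arrays, which enter neither, left r at -0.282, and leaving out any 1 of the 8 arrays left it at -0.257 or below. The values without each array argue against 1 array as the whole cause. With the removed difference (replicate 1 minus 2), the aba2 effect correlated at -0.377 and the ein2 effect at 0.275. An axis of array variation of that kind may therefore contribute. The difference rests on 2 arrays, and its own noise can leave part of such an axis behind, so -0.282 cannot exclude it. Chance likeness between array differences stays open: with the 4 arrays of each comparison split so that each side held 1 mutant and 1 wild-type array, which leaves no genotype effect, the correlation reached at most 0.199 in size, but only 4 combinations exist, too few for a share under 0.05. A biological explanation, that genes responding to ethylene perception move the opposite way when ABA is low, also stays open. It was examined on the 63 probe sets called in etr1, which were picked without their ein2 values. Turned by their direction in etr1, they had a median change of -0.117 in aba2 (37 of 63 opposite). Fry gave p = 0.000249 from limma's pooled model, where an exact permutation of 2 arrays against 2 could not give a p below 0.333. The p goes with this explanation while the size is small. Against Col-0 the median was -0.045, but the same Col-0 arrays picked the 63 probe sets, and their noise draws this median toward the etr1 direction. It therefore cannot show whether the size depends on the wild type. The 24 called in both etr1 and ein2 had -0.315 (16 of 24 opposite), but they were picked in part by ein2 and so restate its correlation with aba2. A state of the Col-0 14 d arrays, the control of ein2, was not tested as a cause. The age difference shared 23 calls in the same and 3 in opposite directions with aba2, and 2 and 15 with ein2. For age and ein2 r was -0.165, where sharing the Col-0 14 d arrays alone gave a simulated -0.498. The simulation gave every group the same spread. On the arrays the shared Col-0 14 d replicates differed least (SD of the log2 difference 0.227) and those of Col-0 at 12 d most (0.606). The simulated value therefore overstates what sharing gives. Opposite calls of that pair are expected in part from the shared arrays, but how large this part is cannot be told.

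The difference between Col-0 at 14 d and 12 d comes with a difference in 1 of 4 spiked transcripts compared. The lowest bioC signal at 14 d was 1.82 times the highest at 12 d, while the other 3 overlapped between the ages. A batch of labelling or hybridization therefore cannot be told apart from age, since the labels give no batch and no array breaks the split. Breakdown of RNA is argued against by 3'/5' ratios that overlapped between the ages (GAPDH at most 1.01 at 14 d, with 0.939 to 1.24 at 12 d; actin 2.13 to 2.64 and 2.02 to 3.71). More of an early stress or handling response in the 14 d plants stays open: the calmodulin-like genes were higher (median 0.85; with ZAT10, 4 of 6 called), but these genes prompted the explanation, so they do not test it. Growth between the ages stays open and was not tested.

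Control probe sets outside the comparisons also showed signals above those of the control arrays. The 25S rRNA probe set gave 502 on ein2 replicate 1 (Col-0 at 14 d gave 219 to 242) and 3540 on aba2 replicate 2 (Col-7 gave 148 to 512, but replicate 2 of the wild type Col-0 at 12 d gave 4442, so the signal is not peculiar to aba2). On the Col-0 arrays of 14 d, bioC gave 1140 and 1130 at its 5' probe set and 1100 and 1030 at its 3' probe set, above both Col-0 arrays of 12 d. The 5S rRNA probe set gave 216 and 431 on the same 14 d arrays, against 31.8 and 42.4 at 12 d. Over all arrays its signals did not overlap between the ages (216 to 431 at 14 d, 7.07 to 46.5 at 12 d). What this means for the plastid- and mitochondria-encoded sets was not tested.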

How the results depend on the processing

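Array weights, the other controls for etr1 and leaving out arrays for gene lists were chosen after the data were seen; the other alternatives were fixed before. Among the genes named for their largest changes, no call changed direction under the alternatives run. Each under its alternatives, these calls kept their side of the threshold in 148 cases and lost it in 43 in etr1, 143 and 36 in ein2, 104 and 62 in aba2, and 154 and 34 with age. All signs of these genes stayed. Members named only from a list are not in these counts, and some that did not pass changed sign, such as PDF1.2b in etr1. Of the sets that passed with all arrays or under the alternative, only the autophagy genes between the wild types changed direction. They turned to up without Col-0 12 d replicate 2, with a median of -0.047, against -0.498 without replicate 1. Set tests kept their side in 1396 cases, lost the call in 78 and gained it in 20. The 1396 include lists that passed neither way, and an uncalled list that changed direction is in none of these counts. For aba2 and etr1, r went from -0.0444 to 0.226 without Col-0 12 d replicate 2. With Col-0 as control it was 0.11, but there the shared Col-0 arrays alone gave a simulated 0.501, so this does not show a turned balance. Signals near the offset limit what can be seen of dim transcripts. Except where the construction shows the cause (fewer arrays, fewer probe sets, a spread taken from fewer groups), the cause was not tested.

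Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 6 to 417 calls in etr1, 12 to 17 in ein2, 4 to 58 in aba2, 54 to 586 in aba2 against Col-0, 0 to 465 between the wild types and 143 to 1462 with age. Lists past the threshold numbered 1 to 5 in etr1, 4 to 7 in ein2, 1 to 4 in aba2, 0 to 1 between the wild types and 1 to 4 with age. Differences numbered 0 to 12 (etr1 and ein2), 15 to 851 (aba2 and etr1) and 25 to 158 (aba2 and ein2). For etr1 and ein2, r was 0.118 to 0.477 with 5 to 53 calls shared in the same and 0 to 0 in opposite directions; for aba2 and etr1 -0.282 to 0.226, with 0 to 10 and 0 to 43; for aba2 and ein2 -0.377 to -0.257, with 0 to 1 and 1 to 9.

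With array weights (0.343 for Col-0 12 d, 2.08 for Col-0 14 d), calls numbered 31 in etr1, 319 in ein2, 40 in aba2, 40 in aba2 against Col-0 and 355 with age; differences 4 (etr1 and ein2), 27 (aba2 and etr1) and 344 (aba2 and ein2); shared calls 2 opposite for etr1 and ein2, 1 same and 2 opposite for aba2 and etr1, 1 same and 13 opposite for aba2 and ein2. With only the groups compared in the fit, calls numbered 0 in etr1, 368 in ein2, 7 in aba2, 6 in aba2 against Col-0 and 121 with age; differences 0, 16 and 310 in the same order; shared calls 0 same for etr1 and ein2, 0 and 0 for aba2 and etr1, and 2 opposite for aba2 and ein2. The 2-fold rule gave 95 in ein2, 10 between the wild types and 331 with age.

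The filter at the 60th percentile gave 41 calls in aba2, 3 opposite calls for aba2 and etr1, and 2 lists in etr1 (4 in the report), 4 in ein2 (8), 1 in aba2 (2) and 2 with age (4). Without a filter there were 88 differences between aba2 and ein2, 3 opposite calls for aba2 and etr1, r of -0.287 for aba2 and ein2, and 7 lists with age. An offset of 150 left 1 difference between etr1 and ein2, and quantile normalization 1 list in aba2. Col-0 as the control of aba2 gave 221 calls, r of 0.11 with 6 same and 2 opposite calls for aba2 and etr1, and r of -0.207 for aba2 and ein2; both wild types averaged gave 255. Against Col-7, etr1 had 112 calls, and against both wild types 165. With an estimated correlation 0 lists passed in any of the 5 comparisons, and with fry 0 in etr1, in ein2 and between the wild types. In aba2 and with age some lists passed with fry, but the plastid- and mitochondria-encoded sets did not. Their unadjusted fry p was 0.0195 and 0.0544 in aba2, and 0.0124 and 0.0161 with age.

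The labels give the replicate numbers no shared batch, and the numbers were not treated as pairs: differences between replicates correlated at 0.542 for Col-0 and Col-7 at 12 d, 0.486 for Col-0 12 d and aba2 and 0.341 for Col-7 and aba2, a hint that the number ties these 3 groups, but at -0.0177 for Col-0 12 d and etr1, -0.0724 for Col-0 14 d and ein2 and -0.264 for ein2 and Col-7. With the replicate number as a block, calls numbered 72 in etr1, 55 in ein2, 75 in aba2, 250 in aba2 against Col-0, 0 between the wild types and 944 with age; differences 1, 80 and 159; and aba2 and etr1 shared 5 calls in the same direction.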

Other observations

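In this part, the test of carbon supply was chosen before the values it measures were seen, though after the array pattern itself, and the test of RNA breakdown after; the other comparisons were chosen after the results were seen.

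Transcripts higher in aba2 overlapped with those higher in the older wild type. Between aba2 against Col-7 and Col-0 at 14 d against 12 d, which share no arrays, 23 probe sets were called in the same direction and 3 in opposite directions by limma. Independent lists would share 2.09 in the same direction. The effects correlated at r = 0.26 across probe sets. CML42 (1.56 in aba2, 0.85 with age), SIS (1.51 and 2.03), AT2G24600 (1.47 and 3.07) and AT5G28630 (2.12 and 1.90) rose in both. Against Col-0, where the 12 d arrays are shared, 141 were called in the same direction (independent lists would share 9.23). There r was 0.45 where the shared arrays alone gave 0.502, and the covariance was 0.0860 against a simulated 0.0296. The simulation gave every group the same spread, while the shared Col-0 12 d replicates differed most (SD of the log2 difference 0.606). Its covariance is therefore too low a reference, and an excess over sharing cannot be shown. WRKY53 rose against Col-0 in aba2 (2.36 ± 0.211, adjusted p = 0.00131) but not against Col-7 (0.77 ± 0.211, adjusted p = 0.17).

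Of the 25 lists, 14 passed as sets in none of the 5 comparisons of 2 groups. Their lowest camera adjusted p-values were 0.0756 for cold and dehydration genes (lower in etr1), 0.0813 for SWEET sugar transporters (higher with age) and defensins (lower with age), 0.0948 for ethylene perception and signalling, 0.1 for gibberellin, 0.12 for RALF-like peptides, 0.152 for bZIP factors, 0.158 for CYP71B cytochromes P450, 0.306 for expansins, 0.371 for tau glutathione S-transferases, 0.486 for serine carboxypeptidase-like genes, 0.504 for auxin and for peroxidases, and 0.623 for ubiquitin-conjugating enzymes. Among unnamed probe sets, 1 rose in aba2 by 2.85 ± 0.202 (adjusted p = 0.000588). Another fell by 3.09 ± 0.327 in ein2 and by 2.01 ± 0.327 in etr1 on the log2 scale.

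The 2 Col-0 arrays of 12 d differed more than other replicates (SD of the log2 difference 0.606), and the counts in etr1 and with age depend on them. Breakdown of RNA in replicate 2 stays open: its GAPDH 3'/5' ratio of 1.24 lay above the 0.939 to 1.12 of the other 10 arrays, but its actin ratio of 2.65 lay within their 2.09 to 3.71. Both upper limits came from 1 array, Col-7 replicate 2, a control of aba2. The next highest ratios were 1.03 for GAPDH (etr1 replicate 2) and 2.64 for actin (ein2 replicate 2). The actin ratio therefore does not speak against breakdown. The 25S rRNA signal of Col-0 replicate 2 was 4442 against 222.75 in replicate 1 (19.9-fold), which is open to the same reading, though aba2 replicate 2 had 3540 with low ratios (GAPDH 0.941, actin 2.09). A different state of carbon supply or light at harvest, the only biological explanation tested, may contribute and stays open. Of 12 measured genes that rise in darkness or starvation (autophagy genes, IVD and D2HGDH), 100% were higher in replicate 2, by a median of 0.40 on the log2 scale, against 48.5% of all probe sets.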
